A study of Mus musculus with 39 samples.

How the data were processed

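Poly-A RNA of liver, skeletal muscle and white adipose tissue (WAT) was sequenced in 39 libraries of 18 mice, 1 library per mouse and tissue. Per the labels, RNA came from a column kit for liver and muscle and from a different kit for WAT, with 300 ng of total RNA as input. The labels describe directional and non-directional library preparation and do not say which was used. Per the submitters' processing notes, the authors called bases with CASAVA 1.8, aligned reads with HISAT2 2.0.5 to mm39 and tested expression with DESeq2 1.20.0. The tool that assigned reads to genes and the annotation release were not given. The 6 deposited tables, 1 per tissue and pair of arms, listed 23265 and 23523 genes in liver, 23580 and 23221 in muscle and 25633 and 26333 in WAT. Per the file headers, expression was in FPKM, fragments per kilobase of gene scaled to library size, as the authors computed it. The deposited tables also held the authors' log2 fold change, and the authors' p-value with its adjusted value. Beside these stood the gene length in bases used by the authors, per the file headers. All 39 columns matched a sample, with 0 left over. The PCOS vehicle columns of a tissue were identical in its tables, with a largest difference of 0.

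FPKM multiplied by gene length was a whole multiple of 1 step per library for 100% of values, within a tolerance of 0.001. Reads were recovered from these steps and used for depth, for the filter and for a count-based alternative. The library size implied by the authors' FPKM was 0.776 to 0.931 times the recovered reads in liver, 0.697 to 0.864 in muscle and 1.26 to 1.59 in WAT, with a geometric mean of 1.001 over all libraries. Values were compared within a tissue, and only differences between arms were compared across tissues. A gene listed at 0 in a library allows up to 3 reads there, and this covers counting error only. Spearman correlations between libraries of a tissue ranged from 0.860 to 0.925 in liver, 0.913 to 0.946 in muscle and 0.853 to 0.951 in WAT, and no library was a copy of another.

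The comparisons, tests, gene lists and alternatives were written down before the data were examined. The plan named a count-based test for counts and limma with a trend on log2(value + 0.5) for normalized values. Since the tables held FPKM, limma 3.58.1 in R 4.3.3 was used on log2(FPKM + 0.5) without further scaling. The edgeR test and a fit with DESeq2 that had been foreseen were not run, and voom served as the count-based alternative. Each pair of arms was fitted alone. Genes passed the filter at 10 reads, scaled to depth, in as many libraries as the smaller arm and 15 reads in total. P values were adjusted by Benjamini and Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05 with no minimum fold. All tests were two-sided.

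The 38 gene lists of pathways and cell types, 24 of them for all tissues, were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists of that comparison. A list needed at least 5 measured members. Camera with an estimated correlation and fry were run beside it, and members were also adjusted over the list alone. Named genes followed a fixed rule. It took the 6 largest rises and the 6 largest falls among called protein-coding genes with a mean of at least 1 CPM of recovered reads, groups that did not overlap and an established symbol. It added up to 4 called members of each list described, or up to 2 members with the lowest p, given as not passing. In roxadustat comparisons it added fixed HIF target and metabolic genes, and, where fewer than 6 genes passed, the 5 with the lowest p. Some of the genes it named were left out of the text. Of the named genes many overlap another annotated gene or have paralogs.

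Opposite effects were measured in a fit of the 3 arms of a tissue, with the PCOS vehicle libraries shared, simulated and split. Differences between tissues were tested as the interaction of tissue and arm, with mouse as a block as an alternative. Mouse numbers are shared between tissues, since a mouse gave up to 3 libraries. The correlation between 2 tissues of the same mouse, after removing arm means, had a median of -0.0122 for liver with muscle over 12 mice, 0.0803 for liver with WAT over 9 and -0.0255 for muscle with WAT over 9. No mouse was in more than 1 arm of a tissue, so the comparisons within a tissue were unpaired.

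The fit was tested on simulated data with 200 changed genes. It recovered 12% of 2-fold and 66% of 4-fold changes in liver, 52% and 82% in muscle and 16% and 64% in WAT for PCOS against control, with 4, 11 and 4 false calls. Camera called 20 of 20 raised and 0 of 100 unchanged simulated lists. The simulated genes varied independently of each other, so this does not test camera on lists of correlated genes. Other splits of the real libraries called a median of 7, 6 and 6 lists for PCOS in liver, muscle and WAT. For roxadustat these medians were 9, 5.5 and 7. For the liver minus muscle difference 68.4% of 4-fold changes were recovered for PCOS and 54.8% for roxadustat.

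Alternatives fixed beforehand were pseudocounts of 0.1 and 1, scaling by the median ratio (RLE), no filter, voom with sample quality weights on recovered reads, a fit of all 3 arms and leaving out each mouse in turn. Added after the data were seen were sample quality weights on log2 FPKM, a term for libraries with fewer than 1500 genes of 1 to 3 reads, tissue differences in the mice with both tissues only, and the contrast of roxadustat with control vehicle. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 read the tables, and matplotlib 3.10.9 drew the figures.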

Results

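RNA levels were measured in liver, skeletal muscle and white adipose tissue (WAT) of C57Bl6/J mice in 3 arms. Polycystic ovary syndrome (PCOS) was modelled with letrozole, an aromatase inhibitor, given before puberty. From 12 weeks of age PCOS mice received vehicle or roxadustat by mouth for 6 weeks, and a control arm received vehicle. Roxadustat inhibits the prolyl hydroxylases that mark hypoxia-inducible factor (HIF) for degradation. Liver and muscle had 4 mice in each arm, and WAT had 4 control, 6 PCOS vehicle and 5 roxadustat mice. Each replicate was a separate mouse, and 9 of the 18 mice gave libraries of all 3 tissues. The 39 libraries held 12389970 to 19350634 reads in liver, 14332757 to 18627919 in muscle and 13664558 to 19639244 in WAT. Genes with at least 1 read numbered 15334 to 19504 in liver, 18571 to 20053 in muscle and 14082 to 21621 in WAT. Expression is given as mean FPKM ± SD over mice, fold as the ratio of mean FPKM, and log2 difference with its SE from limma. Positions refer to mm39.

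The first question in liver was how the PCOS model changed expression under vehicle. Genes with sex-biased expression in liver shifted toward the male-typical pattern. Cyp2b13 (ENSMUSG00000040583, chromosome 7, 25760922 to 25795622), a cytochrome P450 typical of female liver, fell from 171 ± 27.5 FPKM in controls to 0.402 ± 0.358 in PCOS mice (n = 4 and 4), with a log2 difference of -7.64 (SE 0.271, adjusted p = 2.37e-07). The male-typical Cyp2d9 (ENSMUSG00000068086, chromosome 15, 82317638 to 82341046) rose 39.1-fold, from 13.1 ± 0.8291 to 512 ± 204 FPKM, a log2 difference of 5.15 (SE 0.260, adjusted p = 2.20e-06). Mup7 (ENSMUSG00000073842, chromosome 4, 60066469 to 60070475), a major urinary protein gene, rose from 1.30 ± 1.04 to 920 ± 510 FPKM, a log2 difference of 9.01 (SE 0.499, adjusted p = 3.72e-06).

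All 30 measured members of the female-biased liver list were lower in PCOS liver, with a median log2 difference of -4.19. Of them 19 passed over all genes and 26 adjusted over the list alone, and camera gave an adjusted p of 1.54e-55, or 0.0131 with an estimated correlation. The list included the sulfotransferase genes Sult2a1, which fell from 189 ± 96.8 to 0.578 ± 0.732 FPKM, and Sult3a1, which fell from 123 ± 74.5 to 0.757 ± 1.16 FPKM. Sult2a2 fell by a log2 difference of -8.60 (SE 0.503, adjusted p = 4.44e-06). Cyp3a41b fell from 76.8 ± 34.1 to 0.195 ± 0.132 FPKM. Of the 26 measured male-biased genes 25 were higher, with a median log2 difference of 2.93. Over all genes 18 rose, and adjusted over the list alone 24 rose and 1 fell. Camera gave an adjusted p of 1.66e-42, and an adjusted p of 0.0774 with an estimated correlation. Cyp4a12a (ENSMUSG00000066071, chromosome 4, 115156243 to 115190012), an arachidonic acid hydroxylase, rose from 0.325 ± 0.631 to 71.5 ± 30.6 FPKM. Cyp4a12b was listed at 0 in all 4 control libraries and rose to 14.9 ± 5.45 FPKM. The steroid dehydrogenase gene Hsd3b5 rose from 2.90 ± 3.59 to 116 ± 61.4 FPKM. Mup, Cyp4a12, Cyp3a41, Sult2a and Hsd3b genes have close paralogs, as have Cyp2b13 and Cyp2d9, so the share of each member within its family is uncertain. Cyp2b13, Cyp2d9, Sult2a1, Sult2a2, Sult3a1 and Hsd3b5 also overlap another annotated gene, so a part of their signal is uncertain too.

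Outside these lists, Alas2, which starts haem synthesis in erythroid cells, rose 4.36-fold to 23.4 ± 4.80 FPKM (adjusted p = 0.00528). In the bile acid list, 2 of 20 measured members passed over all genes and 3 adjusted over the list alone. The members went both ways, 12 higher and 8 lower, and the camera adjusted p was 0.735. Slco1a1, an organic anion transporter, rose 4.62-fold from 13.6 ± 8.50 to 62.8 ± 7.91 FPKM (adjusted p = 0.0155). Cyp8b1, the sterol 12-alpha-hydroxylase of bile acid synthesis, rose 2.18-fold from 82.9 ± 17.3 to 181 ± 33.1 FPKM (adjusted p = 0.0277). Alas2 and Slco1a1 overlap another annotated gene. Oxidative phosphorylation genes were higher in 50 of 56 members, with a median log2 difference of 0.46. Of those genes 0 passed over all genes in limma and 7 rose adjusted over the list alone (camera adjusted p = 6.58e-13, or adjusted p = 0.948 with an estimated correlation). Cholesterol synthesis genes were lower in 21 of 24 members, with a median of -0.39. Of them 0 passed over all genes in limma and 1 fell adjusted over the list alone (camera adjusted p = 0.000263, or adjusted p = 0.948 with an estimated correlation). Extracellular matrix genes were lower in 18 of 23 members (camera adjusted p = 0.0465, or adjusted p = 0.948 with an estimated correlation). That call ended without vehicle mouse 773 (0.279) or 785 (0.149) or control mouse 802 (0.434). The HIF target list showed no common direction in liver, with 17 of 35 members higher and a camera adjusted p of 0.858.

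Across liver, limma called 115 of 14021 genes, 62 higher and 53 lower in PCOS mice, and in all 115 the values of the groups did not overlap. The deposited table of the authors' own test held 318 genes under an adjusted p of 0.05. Fitted with all 3 arms, limma called 21 genes. Of the 16 named genes that passed, 3 (Cyp2b13, Mup12 and Sult2a2) kept their calls in every alternative fixed beforehand. The call of Slco1a1 ended without vehicle mouse 773, 785 or 814 or control mouse 789. That of Cyp8b1 ended without vehicle mouse 770, 785 or 814 or control mouse 789, 801 or 802. Their limma adjusted p went up to 0.0695 and 0.114 over the alternatives fixed beforehand. Libraries with fewer than 1500 genes of 1 to 3 reads numbered 1 of 4 in the PCOS vehicle and 3 of 4 in the control arm, and a term for them left 92 genes.

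**Figure D1:**
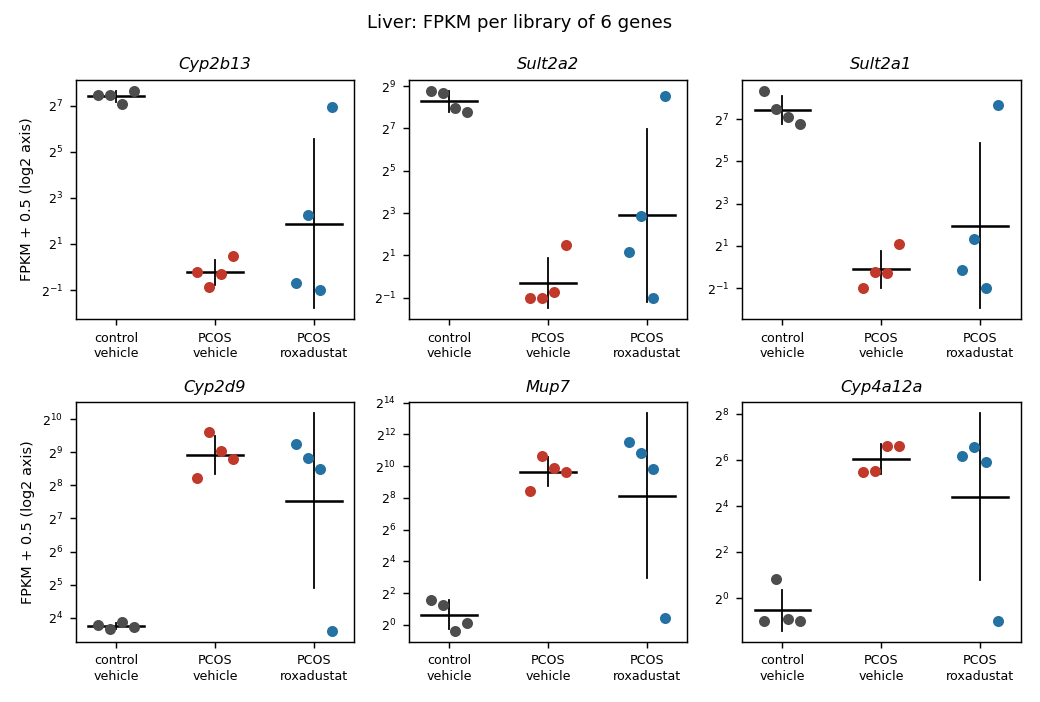
FPKM + 0.5 on a log2 axis for Cyp2b13, Sult2a2, Sult2a1, Cyp2d9, Mup7 and Cyp4a12a in each liver library of the control vehicle, PCOS vehicle and PCOS roxadustat arms (4 mice each), with the geometric mean as a bar and 1 SD on the log2 scale as a vertical line. Roxadustat mouse 808 sits with the controls in each panel, at 11.7 FPKM of Cyp2d9 against 360 to 602 FPKM in the other 3 roxadustat mice.

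In skeletal muscle the same contrast of PCOS vehicle with control vehicle was made in 4 and 4 mice. Actr3b (ENSMUSG00000056367, chromosome 5, 25964995 to 26055686), an actin-related protein of the Arp2/3 type, rose 10.3-fold from 1.08 ± 0.292 to 11.2 ± 2.92 FPKM, a log2 difference of 2.87 (SE 0.207, adjusted p = 0.000574). Amd1 (ENSMUSG00000075232, chromosome 10, 40163454 to 40178184), the S-adenosylmethionine decarboxylase of polyamine synthesis, rose 3.92-fold to 330.5 ± 75.2 FPKM from 84.2 ± 19.4, a log2 difference of 1.97 (SE 0.217, adjusted p = 0.00700). Cbr2, a carbonyl reductase, rose 2.64-fold from 8.78 ± 0.678 to 23.2 ± 1.49 FPKM (log2 difference 1.35, SE 0.102, adjusted p = 0.000574). Stc2, a secreted glycoprotein and HIF target, fell from 2.19 ± 0.280 to 0.612 ± 0.169 FPKM (log2 difference -1.28, SE 0.141, adjusted p = 0.00700). Amd1 has the close paralog Amd2, and Mettl21c and Cdk19 overlap another annotated gene, so their own share of the signal is uncertain.

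The lysine methyltransferase gene Mettl21c rose 2.81-fold to 16.1 ± 4.11 FPKM, the Mediator kinase gene Cdk19 rose 2.57-fold to 8.46 ± 1.14 FPKM, and Odf3l2 rose 7.12-fold to 7.23 ± 3.62 FPKM. In the polyamine list 10 of 12 members were higher, with a median log2 difference of 0.20. Amd1 alone passed over all genes, and 3 rose adjusted over the list alone (camera adjusted p = 0.000291, or adjusted p = 0.409 with an estimated correlation). Adipocyte markers were lower in 17 of 18 members, with a median of -0.59. The adipsin gene Cfd, which did not pass, stood at 28.4 ± 15.1 against 141 ± 103 FPKM. In limma 0 markers passed over all genes or adjusted over the list alone (camera adjusted p = 5.98e-06, or adjusted p = 0.409 with an estimated correlation). Genes of fatty acid and triglyceride synthesis were lower in 17 of 23 members, with a median of -0.25. Of these, Pnpla3 stood at 2.44 ± 0.800 against 4.90 ± 1.21 FPKM without passing. The list had a camera adjusted p of 0.000629, or an adjusted p of 0.409 with an estimated correlation. Extracellular matrix genes were lower as well, in 23 of 25 members with a median of -0.22 (camera adjusted p = 0.000462, or adjusted p = 0.612 with an estimated correlation), a call that ended without vehicle mouse 773 (0.293). Macrophage markers were lower in 11 of 12 members without passing as a list (camera adjusted p = 0.0588, or adjusted p = 0.699 with an estimated correlation). Camera also called glycolysis genes higher (14 of 19 members, adjusted p = 0.00514). It called insulin signalling (17 of 24, 0.0457) and unfolded protein response genes (12 of 20, 0.0457) lower. Each of these calls ended in some fit that left out a mouse, and none held with an estimated correlation.

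Oxidative phosphorylation genes were higher in 55 of 58 members of the list in muscle, with a median log2 difference of 0.17 (camera adjusted p = 9.95e-06, or adjusted p = 0.699 with an estimated correlation). Genes of muscle atrophy and protein breakdown were lower in 13 of 17 members. Among them Klf15, a transcription factor of muscle catabolism, stood at 20.5 ± 2.36 against 27.2 ± 2.09 FPKM without passing. The list's camera adjusted p was 0.00235, or an adjusted p of 0.409 with an estimated correlation. All 5 measured erythroid markers were higher, with a median of 0.92 (camera adjusted p = 0.000231, or adjusted p = 0.409 with an estimated correlation). The haemoglobin gene Hbb-bs stood at 324 ± 148 against 172 ± 87.6 FPKM without passing. The HIF target list showed no common direction, with 19 of 41 members higher (camera adjusted p = 0.746). Stc2 alone passed over all genes and 2 fell adjusted over the list alone.

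In muscle limma called 14 of 13438 genes, 12 higher and 2 lower in PCOS mice, and the values of the groups did not overlap in any of the 14. The deposited table of the authors' test held 92. The count was 22 without vehicle mouse 770, 7 without vehicle mouse 785 or 814 or control mouse 802 or 804, 6 without control mouse 789 and 8 without control mouse 801. It was 42 with voom on recovered reads, which also used sample quality weights, and 27 with such weights on log2 FPKM. With no filter on low values it was 5. The calls of Mettl21c and Odf3l2 ended without vehicle mouse 785 or 814 or control mouse 789, 802 or 804. That of Odf3l2 also ended without vehicle mouse 773 or control mouse 801. Their limma adjusted p went up to 0.117 and 0.229 over the alternatives fixed beforehand.

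**Figure D2:**
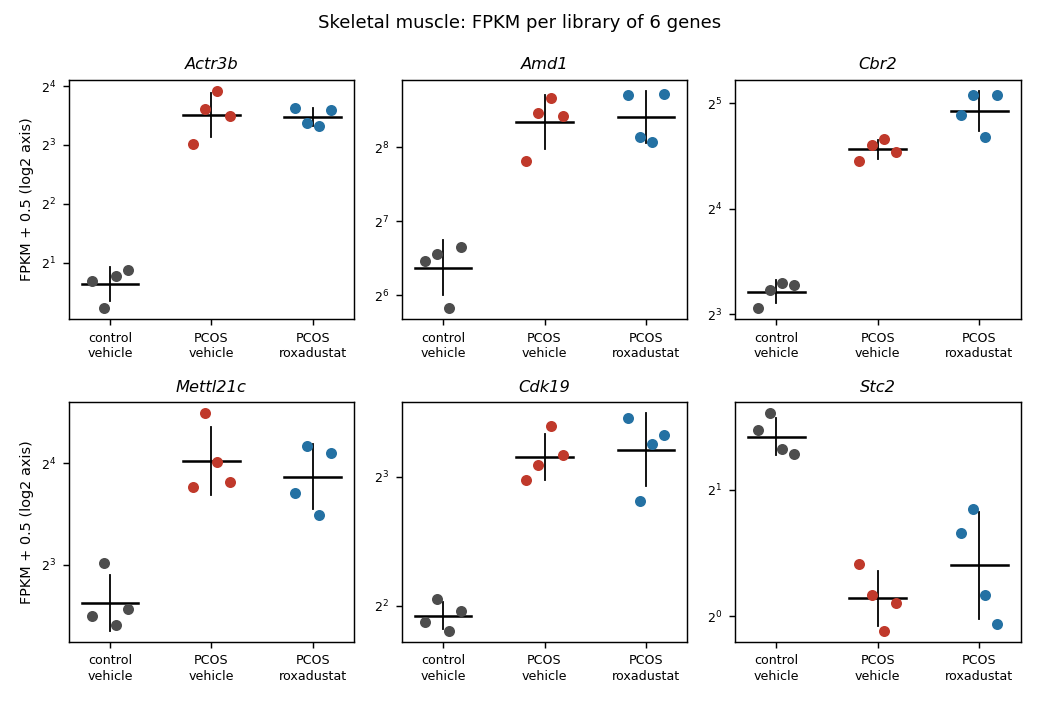
FPKM + 0.5 on a log2 axis for Actr3b, Amd1, Cbr2, Mettl21c, Cdk19 and Stc2 in each muscle library of the control vehicle, PCOS vehicle and PCOS roxadustat arms (4 mice each), with the geometric mean as a bar and 1 SD on the log2 scale as a vertical line. Actr3b rose from a mean of 1.08 FPKM in controls to 11.2 FPKM in PCOS vehicle mice, and the values of these groups did not overlap in any panel.

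In WAT the contrast of PCOS vehicle with control vehicle covered 6 and 4 mice. Krt19 (ENSMUSG00000020911, chromosome 11, 100031636 to 100039491), a keratin of epithelial and mesothelial cells, fell from 9.96 ± 2.99 to 1.32 ± 0.653 FPKM, a log2 difference of -2.56 (SE 0.293, adjusted p = 0.00453). Elovl6 (ENSMUSG00000041220, chromosome 3, 129326004 to 129432144), a fatty acid elongase, fell from 58.4 ± 17.0 to 8.40 ± 6.42 FPKM, a log2 difference of -3.03 (SE 0.499, adjusted p = 0.0289). The fructose transporter gene Slc2a5 fell from 7.47 ± 1.63 to 1.19 ± 1.12 FPKM (log2 difference -2.48, SE 0.431, adjusted p = 0.0367). The complement gene C7 rose 20.96-fold from 0.0769 ± 0.0888 to 1.61 ± 0.648 FPKM (log2 difference 1.82, SE 0.253, adjusted p = 0.0136). The protease inhibitor gene Serpine2 rose 2.97-fold from 3.24 ± 1.01 to 9.64 ± 3.71 FPKM (SE 0.264 on the log2 scale, adjusted p = 0.0471). Elovl6, Prelp and Vsig8 overlap other annotated genes, so a part of their signal is uncertain.

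Among other genes that fell were the growth factor gene Mdk, from 7.56 ± 4.67 to 0.798 ± 0.512 FPKM, the nerve growth factor receptor gene Ngfr, from 4.05 ± 1.48 to 0.693 ± 0.452 FPKM, and the ferric reductase gene Cybrd1, from 2.11 ± 1.92 to 0.0646 ± 0.0547 FPKM. The matrix proteoglycan gene Prelp rose 5.76-fold to 141 ± 73.2 FPKM, and Vsig8 rose from 0.00597 ± 0.0119 to 1.62 ± 0.837 FPKM. Fatty acid and triglyceride synthesis genes were lower in 21 of 23 members, with a median log2 difference of -0.77. Elovl6 alone passed over all genes and 11 fell adjusted over the list alone (camera adjusted p = 7.01e-09, or adjusted p = 0.280 with an estimated correlation). Oxidative phosphorylation genes were lower in 57 of 58 members, with a median of -0.66. In limma 0 passed over all genes and 8 fell adjusted over the list alone (camera adjusted p = 8.11e-19, or adjusted p = 0.306 with an estimated correlation). Mitochondrially encoded transcripts took 9.85 ± 2.68% of reads in PCOS vehicle and 18.02 ± 4.62% in control WAT.

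Camera also called lists of cell-type markers in WAT, but none held with an estimated correlation. All 7 mesothelial and ovarian markers were lower, with a median of -1.24. Of them 0 passed over all genes in limma and 6 fell adjusted over the list alone (camera adjusted p = 2.34e-07, or adjusted p = 0.134 with an estimated correlation). Mesothelin (Msln), not passing, stood at 1.30 ± 0.846 against 6.42 ± 2.78 FPKM. Epithelial markers were lower in 5 of 6 members, with Krt19 passing over all genes and 4 falling adjusted over the list alone (camera adjusted p = 1.28e-05, or adjusted p = 0.108 with an estimated correlation). Macrophage markers were higher in 19 of 20 members, with a median of 0.55. Of these 0 passed over all genes in limma and 5 rose adjusted over the list alone (camera adjusted p = 1.50e-06, or adjusted p = 0.280 with an estimated correlation). Adgre1, the F4/80 gene, did not pass at 5.85 ± 2.66 against 2.33 ± 0.950 FPKM. Adipocyte markers were higher too, in 15 of 18 members with a median of 0.27 (camera adjusted p = 0.0106, or adjusted p = 0.306 with an estimated correlation), a call that ended without vehicle mouse 785 (0.0828) or control mouse 802 (0.0572). Endothelial markers were higher in 13 of 14 members, with a median of 0.34 (camera adjusted p = 0.00421, or adjusted p = 0.444 with an estimated correlation). Extracellular matrix genes were higher in 20 of 26 members, with a median of 0.30 (camera adjusted p = 0.0106, or adjusted p = 0.605 with an estimated correlation), a call that ended without vehicle mouse 770 (0.0559) or control mouse 789 (0.132). Genes of lipoprotein and lipid uptake were higher in 10 of 11 members (camera adjusted p = 0.0106, or adjusted p = 0.280 with an estimated correlation), a call that ended without control mouse 802 (0.0660). In these 4 lists limma passed 0 genes over all genes. Cell cycle genes were higher in 19 of 21 members (camera adjusted p = 4.73e-05, or adjusted p = 0.280 with an estimated correlation). Genes of the unfolded protein response were higher in 17 of 20 members, 2 of which rose adjusted over the list alone (camera adjusted p = 0.00421, or adjusted p = 0.108 with an estimated correlation). HIF target genes were higher in 30 of 40 members, with a median of 0.21. In limma 0 passed over all genes, and 5 rose and 3 fell adjusted over the list alone. The HIF list had a camera adjusted p of 0.0106, or an adjusted p of 0.306 with an estimated correlation, and its call ended without vehicle mouse 785 (0.0639) or control mouse 778 (0.0826). The HIF hydroxylase gene Egln3 did not pass, at 1.39 ± 0.512 against 3.49 ± 0.777 FPKM (adjusted p = 0.0643).

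In WAT limma called 54 of 15603 genes, 14 higher and 40 lower in PCOS mice, with no overlap of the groups' values in any of the 54. The deposited table of the authors' test held 419. The count was 330 without vehicle mouse 785, 26 without vehicle mouse 770, 23 without 814, 17 without 822 and 14 without 796, and 16 without control mouse 778 or 779 and 11 without control mouse 802. Krt19 kept its call in every alternative fixed beforehand. Without control mouse 802 the calls of all other named genes that had passed ended. The count was 940 with sample quality weights on log2 FPKM and 800 with voom, which also used such weights. It was 141 with all 3 arms and 10 with no filter on low values. Libraries with fewer than 1500 genes of 1 to 3 reads numbered 4 of 6 PCOS vehicle and 2 of 4 control mice, and a term for them left 21 genes.

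**Figure D3:**
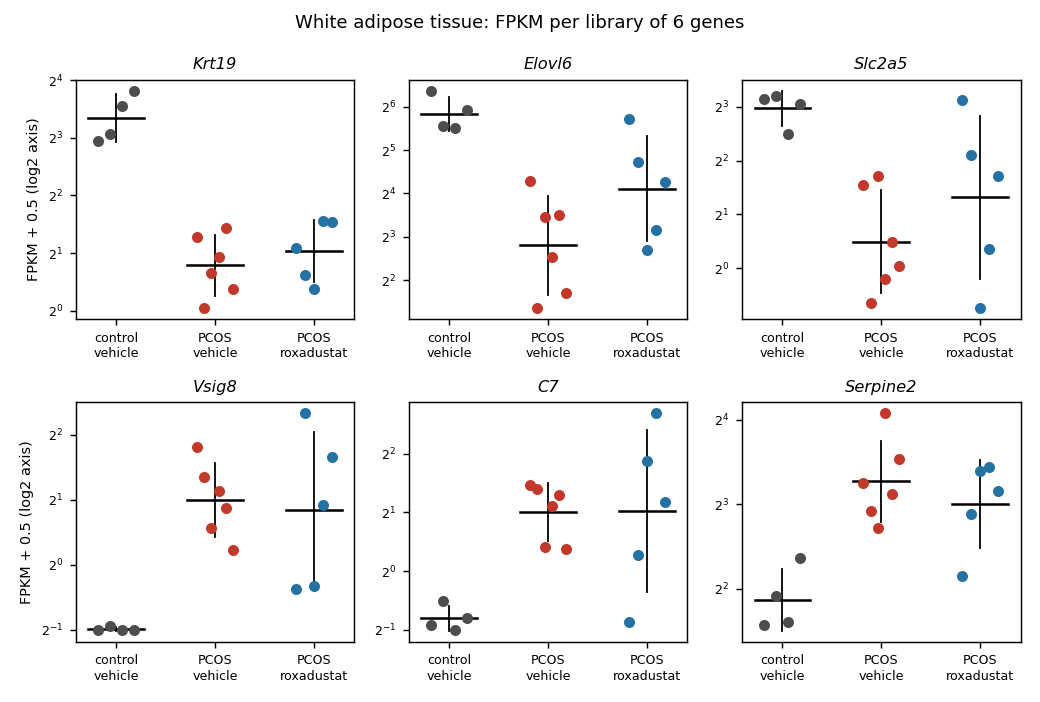
FPKM + 0.5 on a log2 axis for Krt19, Elovl6, Slc2a5, Vsig8, C7 and Serpine2 in each WAT library of the control vehicle (4 mice), PCOS vehicle (6 mice) and PCOS roxadustat (5 mice) arms, with the geometric mean as a bar and 1 SD on the log2 scale as a vertical line. Krt19 fell from a mean of 9.96 FPKM in controls to 1.32 FPKM in PCOS vehicle mice, with no overlap of the values.

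In liver the effect of 6 weeks of roxadustat in PCOS mice was measured against PCOS vehicle in 4 and 4 mice. The HIF hydroxylase gene Egln3 (ENSMUSG00000035105, chromosome 12, 54225767 to 54250646), itself a HIF target, stood at 5.06 ± 1.38 FPKM with roxadustat and 3.33 ± 0.456 with vehicle, a log2 difference of 0.51 that did not pass (adjusted p = 0.9997). The angiogenic factor gene Vegfa stood at 96.2 ± 9.19 against 106 ± 38.9 FPKM and the pyruvate dehydrogenase kinase gene Pdk1 at 12.5 ± 3.43 against 12.0 ± 4.14 FPKM. Hamp (ENSMUSG00000050440, chromosome 7, 30641793 to 30643457), which encodes the iron hormone hepcidin, stood at 4451 ± 1489 against 2890 ± 1731 FPKM (log2 difference 0.91, SE 0.623). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 37.7 ± 15.02 against 27.6 ± 8.63 FPKM. HIF target genes went both ways, with 14 of 34 members higher (camera adjusted p = 0.997).

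The lowest unadjusted p values belonged to genes that included Clec2d, at 128 ± 21.5 against 273 ± 55.6 FPKM, and Tmem88, at 3.41 ± 0.554 against 1.59 ± 0.221 FPKM, neither of which passed. Cholesterol synthesis genes were higher in 23 of 24 members with roxadustat, with a median log2 difference of 0.35 (camera adjusted p = 5.87e-07, or adjusted p = 0.495 with an estimated correlation). Mvk, the mevalonate kinase gene of that pathway, stood at 18.1 ± 3.42 against 10.97 ± 3.11 FPKM. Extracellular matrix genes were higher in 22 of 23 members (camera adjusted p = 3.71e-05, or adjusted p = 0.495 with an estimated correlation). Markers of bile duct and stellate cells were higher in 12 of 13 members, among them the cholangiocyte factor gene Sox9 at 3.14 ± 1.403 against 1.32 ± 0.247 FPKM (camera adjusted p = 0.000192, or adjusted p = 0.410 with an estimated correlation). Iron handling genes were higher in 17 of 20 members (camera adjusted p = 0.00198, or adjusted p = 0.410 with an estimated correlation). Oxidative phosphorylation genes were lower in 43 of 56 members (camera adjusted p = 0.00198, or adjusted p = 0.779 with an estimated correlation). The latter call ended without roxadustat mouse 808 (0.598) or 782 (0.0710) or vehicle mouse 773 (0.706). Camera also called epithelial markers (8 of 10 members, adjusted p = 0.00719), glycolysis (14 of 20, 0.0367) and gluconeogenesis and glycogen (12 of 16, 0.0297) higher. It called heat shock genes (8 of 9, 0.0182) and lymphocyte markers (8 of 12, 0.0229) lower. Each of these calls ended in some fit that left out a mouse, and none held with an estimated correlation. In limma 0 members of these lists passed over all genes or adjusted over the list alone.

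Male-biased liver genes were lower with roxadustat in 24 of 26 members, with a median of -0.50 (camera adjusted p = 0.000479, or adjusted p = 0.670 with an estimated correlation). Female-biased genes were higher in 17 of 20 members, with a median of 0.42 (camera adjusted p = 0.00198, or adjusted p = 0.510 with an estimated correlation). Both calls ended without roxadustat mouse 808, with adjusted p of 0.333 and 0.684, and the male-biased direction turned. The male-biased call also ended without vehicle mouse 773 (0.119). In mouse 808 Mup7 stood at 0.859 FPKM, against 890 to 2890 FPKM in the other 3 roxadustat mice.

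In liver limma called 0 of 14015 genes for roxadustat, with 411 genes at an unadjusted p under 0.05, where chance alone would give about 701. Voom on recovered reads also called 0, and the deposited table of the authors' test held 3. Leaving out any single mouse left the count at 0. On simulated data the same test in this comparison recovered 17% of 2-fold and 58% of 4-fold changes, so most 2-fold changes were not detectable.

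In muscle roxadustat was compared with vehicle in 4 and 4 PCOS mice. Egln3 stood at 16.4 ± 9.85 against 10.6 ± 4.46 FPKM (log2 difference 0.48), Vegfa at 68.3 ± 15.7 against 72.5 ± 12.5 FPKM and Pdk1 at 12.3 ± 0.770 against 11.3 ± 1.29 FPKM, none of which passed. The insulin-responsive glucose transporter gene Slc2a4 stood at 234 ± 18.5 against 214 ± 27.4 FPKM and the hexokinase gene Hk2 at 70.6 ± 10.04 against 68.2 ± 9.08 FPKM. HIF target genes went both ways, with 22 of 41 members higher and a camera adjusted p of 0.866, the mean and the test differing in sign. Slow-fibre genes were lower in all 10 members, with a median log2 difference of -1.28 (camera adjusted p = 2.995e-06, or adjusted p = 0.894 with an estimated correlation). The slow myosin light chain gene Myl3 stood at 1.93 ± 3.30 against 20.2 ± 29.8 FPKM, so its spread exceeded its mean in each group. Extracellular matrix genes were lower in 24 of 25 members (camera adjusted p = 7.72e-06, or adjusted p = 0.894 with an estimated correlation), a call that ended without roxadustat mouse 808 (0.0950) or vehicle mouse 785 (0.114). All 5 measured hepatocyte genes were lower, with a median of -1.14 (camera adjusted p = 0.00745, or adjusted p = 0.894 with an estimated correlation), a call that ended without vehicle mouse 773 (0.702). All 5 erythroid markers were lower, with a median of -0.46 (camera adjusted p = 0.00525, or adjusted p = 0.894 with an estimated correlation), a call that ended without roxadustat mouse 782 (0.0558) or 767 (0.0611) or vehicle mouse 785 (0.246).

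Among the lowest unadjusted p values in muscle were the interferon-induced GTPase gene Iigp1, at 1.26 ± 0.130 against 2.06 ± 0.164 FPKM, and the activin receptor gene Acvr2b, at 1.76 ± 0.325 against 2.86 ± 0.258 FPKM, neither of which passed. Limma called 0 of 13296 genes, with 320 at an unadjusted p under 0.05, and voom on recovered reads also called 0. Chance alone would give about 665 genes at that unadjusted p. The deposited table of the authors' test held 0, and limma called 2 genes with no filter and 1 without vehicle mouse 770. On simulated data the test recovered 53% of 2-fold and 87% of 4-fold changes in muscle.

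In WAT roxadustat was compared with vehicle in 5 and 6 PCOS mice. Egln3 stood at 2.51 ± 1.12 against 1.39 ± 0.512 FPKM (log2 difference 0.65), Vegfa at 39.7 ± 6.75 against 43.5 ± 13.1 FPKM and Pdk1 at 5.62 ± 1.75 against 4.60 ± 1.62 FPKM, none of which passed. The leptin gene Lep stood at 372 ± 129 against 388 ± 241 FPKM and the adiponectin gene Adipoq at 1454 ± 294 against 1646 ± 407 FPKM. HIF target genes went both ways, with 22 of 42 members higher and a camera adjusted p of 0.622, the median and the test differing in sign. Interferon response genes were lower in 20 of 24 members, with a median log2 difference of -0.17 (camera adjusted p = 3.24e-05, or adjusted p = 0.690 with an estimated correlation). The antiviral gene Rsad2 stood at 2.53 ± 0.787 against 3.84 ± 0.734 FPKM. Fatty acid and triglyceride synthesis genes were higher in 21 of 23 members, with a median of 0.23 (camera adjusted p = 9.11e-05, or adjusted p = 0.690 with an estimated correlation). Acly, which supplies acetyl-CoA for that pathway, stood at 127 ± 68.6 against 58.1 ± 35.9 FPKM. Cholesterol synthesis genes were higher in 18 of 23 members (camera adjusted p = 0.000244, or adjusted p = 0.690 with an estimated correlation). Endothelial markers were lower in 12 of 14 members, among them the tight junction gene Cldn5 at 68.3 ± 35.1 against 102 ± 33.4 FPKM (camera adjusted p = 9.11e-05, or adjusted p = 0.690 with an estimated correlation).

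Camera called other lists for roxadustat in WAT too, and none of its calls there held with an estimated correlation. Of 100 splits of the same WAT libraries, the real one included, 32 called at least 9 lists. Erythroid markers were lower in 6 of 7 members, with a median of -0.66 (camera adjusted p = 0.000221, or adjusted p = 0.690 with an estimated correlation), and the call held in all 11 fits that left out a mouse. In liver they were lower in 6 of 7 members as well (camera adjusted p = 0.0297, or adjusted p = 0.635 with an estimated correlation), but that call ended without roxadustat mouse 808 (0.816) or 782 (0.215) or vehicle mouse 770 (0.0541) or 785 (0.431). Macrophage markers were higher in WAT in 17 of 20 members, with a median of 0.22 (camera adjusted p = 0.0119, or adjusted p = 0.809 with an estimated correlation), a call that ended without roxadustat mouse 767 (0.635) or vehicle mouse 785 (0.256). Extracellular matrix genes were higher in 22 of 26 members, with a median of 0.30 (camera adjusted p = 0.00151, or adjusted p = 0.809 with an estimated correlation), a call that ended without vehicle mouse 785 (0.373). Cell cycle genes were lower in 15 of 21 members (camera adjusted p = 0.00179, or adjusted p = 0.690 with an estimated correlation), a call that ended without roxadustat mouse 795 (0.151) or vehicle mouse 814 (0.0755) or 796 (0.0834).

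All 14 immediate early genes were higher with roxadustat in WAT, with a median of 0.28 (camera adjusted p = 0.00179, or adjusted p = 0.690 with an estimated correlation), and the call ended without roxadustat mouse 767 (0.232). In that mouse Fos stood at 9.95 FPKM, against 2.55 to 3.06 FPKM in the other 4 roxadustat mice. In WAT limma called 0 of 15320 genes, with 266 at an unadjusted p under 0.05, where chance alone would give about 766. Voom on recovered reads called 0, and the deposited table of the authors' test held 0. The number of lists called by camera was 9 of 28, or 15 without roxadustat mouse 764 and 14 without roxadustat mouse 782. On simulated data the test recovered 35% of 2-fold and 76% of 4-fold changes in WAT.

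**Figure D4:**
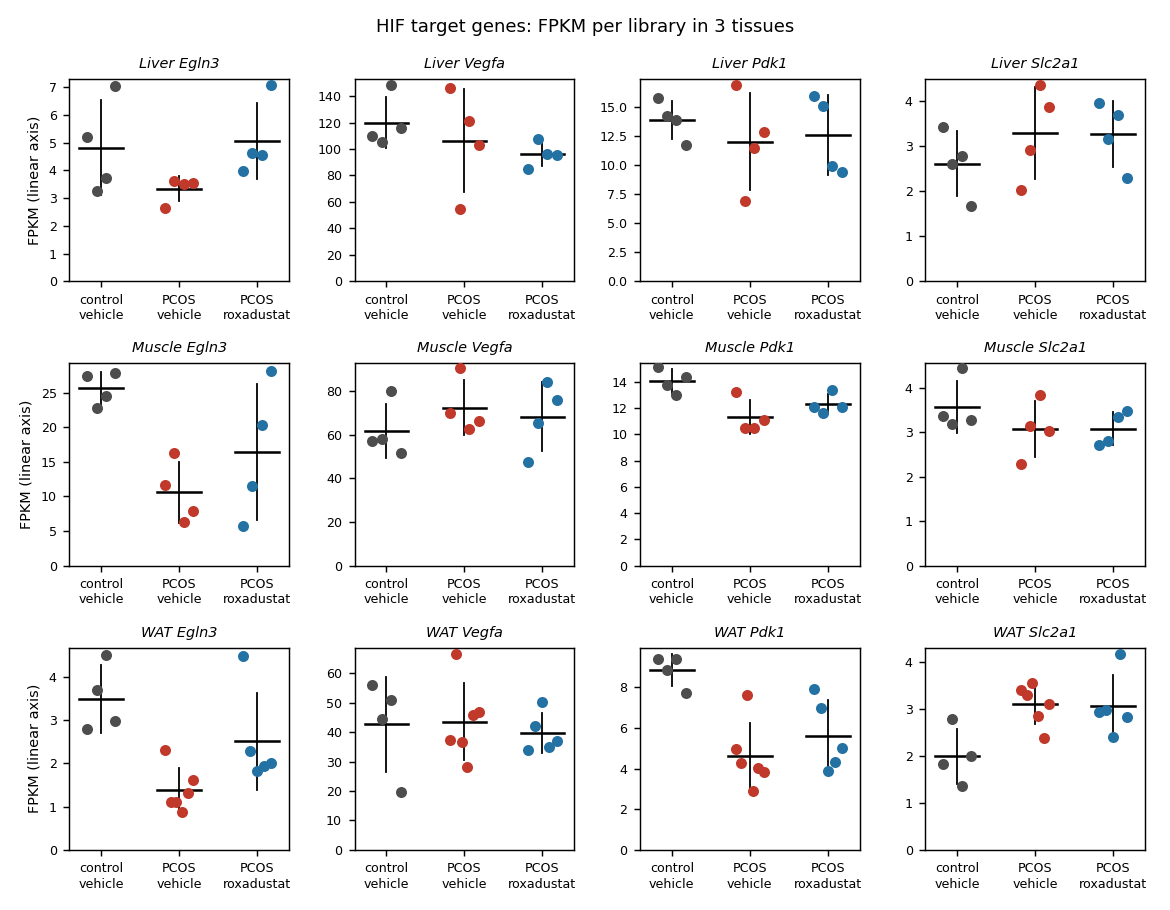
FPKM on a linear axis from 0 for the HIF target genes Egln3, Vegfa, Pdk1 and Slc2a1 in each library of liver, muscle and WAT in the control vehicle, PCOS vehicle and PCOS roxadustat arms, with mean and SD over mice. Egln3 stood at 5.06 ± 1.38 FPKM in liver with roxadustat and 3.33 ± 0.456 FPKM with vehicle, and none of the 4 genes passed for roxadustat in any tissue.

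Whether roxadustat moved genes against the PCOS change was tested in a limma fit of all 3 arms of each tissue. No gene was called in both comparisons with opposite signs. The count was 0 in each tissue because limma called 0 genes for roxadustat there, with 21, 17 and 141 genes called for PCOS in liver, muscle and WAT. At an unadjusted p under 0.05 the 3-arm fits held 353, 354 and 308 genes for roxadustat, of 14784, 13812 and 16353 tested. These are fewer than chance alone would give. Across genes, which are not independent replicates, the log2 differences of PCOS and roxadustat had a Pearson correlation of -0.515 in liver, -0.151 in muscle and -0.0298 in WAT. Both differences share the PCOS vehicle libraries, and unchanged simulated groups with that sharing gave means of -0.478, -0.517 and -0.421. Of 100 simulations 41, 99 and 96 had a correlation as low. With the PCOS vehicle libraries split between the comparisons the mean correlations were -0.141, 0.251 and 0.242. Single splits ranged from -0.269 to -0.0330 in liver, 0.119 to 0.341 in muscle and -0.120 to 0.549 in WAT. Simulated groups were not split in this way. In roxadustat mouse 808 the sex-biased genes Cyp2b13 and Cyp4a12a stood at 124 and 0 FPKM in liver. Without roxadustat mouse 808 the liver correlation was -0.173, the muscle correlation was -0.351 without vehicle mouse 770, and that of WAT was 0.141 without roxadustat mouse 764.

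Differences between tissues in the PCOS effect were tested as interactions in limma. A gene could pass the filter through 1 tissue alone, so a difference can arise where a gene is hardly expressed in the other tissue. Fits with mouse as a block used only mice with libraries of both tissues, which left 12 of 18 libraries where WAT was compared. Cyp2b13 differed by a log2 of -7.58 between liver and muscle (SE 0.308, adjusted p = 2.44e-10) and of -7.61 between liver and WAT (SE 0.301, adjusted p = 9.94e-12). With mouse as a block the adjusted p values were 8.99e-07 and 0.000313. Both Cyp2b13 differences were close to its fall in liver alone. The Actr3b effect was higher in muscle than in liver, with a liver minus muscle log2 of -2.62 (SE 0.303, adjusted p = 0.000194, or 0.0114 with the block). It was also higher in muscle than in WAT by 3.06 (SE 0.425, adjusted p = 0.00776), which with the block was 0.423. The Krt19 effect differed between muscle and WAT by 2.47 (SE 0.387, adjusted p = 0.0115), which with the block was 0.235. The PCOS effect on oxidative phosphorylation genes differed between liver and WAT by a median log2 of 1.11 (camera adjusted p = 2.56e-23, or adjusted p = 0.526 with an estimated correlation). It differed between muscle and WAT by 0.86 (camera adjusted p = 3.25e-20, or adjusted p = 0.260 with an estimated correlation). With the block these camera adjusted p values were 3.01e-17 and 9.10e-13, or 0.656 and 0.443 with an estimated correlation.

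Liver minus muscle held 76 called genes for PCOS, or 52 with the block, 39 without mouse 785 and 50 without mouse 789. Liver minus WAT held 124, or 11 with the block and 24 without it in the 12 libraries of PCOS vehicle and control mice with both tissues. That count was 389 without mouse 785, 82 without mouse 789 or 814 and 77 without mouse 822. Muscle minus WAT held 25, or 0 with the block (limma, 627 at an unadjusted p under 0.05) and 1 in the mice with both tissues. It was 54 without mouse 785, 1 without 802, 7 without 773, 11 without 804, 12 without 778 or 822, 13 without 801 or 814, 14 without 779 and 15 without 796. For roxadustat limma called 0 differences between each pair of tissues, with 403, 337 and 219 genes at an unadjusted p under 0.05 for liver minus muscle, liver minus WAT and muscle minus WAT. With the block these counts were also 0, and without mouse 770 they were 1 for liver minus muscle and 1 for liver minus WAT.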

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

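The tests of the 3 patterns weighed here were chosen only after the results were seen, except that of the second mesothelial markers. The position scale was also chosen afterwards. On it a library lies at 0 with the control mean and at 1 with the PCOS vehicle mean over the called genes. Each control or PCOS vehicle library was placed on genes called without it, so these gene sets differed. A library was picked out where it stood far from the others of its group. Of 452 groups tested 29 held such a library, and about 23 would by chance.

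In liver, the library labelled roxadustat mouse 808 stood apart in 8 measures. Its FPKM was 0.859 for Mup7 (890 to 2890 in the other 3), 0 for Cyp4a12a (59.9 to 94.8), 0 for Cyp4a12b (18.9 to 27.0), 1.87 for Hsd3b5 (64.9 to 107) and 11.7 for Cyp2d9 (360 to 602). It was 67.3 for Cox5b (188 to 214) and 53.1 for Ndufb3 (90.9 to 100.8), and its position was 0.0413 against 0.950 to 1.03.

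That profile was of the control type. A swap with a control library needs a control out of place, and the highest position among the liver controls was 0.0933. A wrong label for the whole mouse was argued against by its muscle library, at 1.17, though over only 14 genes. An effect of roxadustat shared by the treated mice was argued against by the lowest of the other 3 positions, 0.950. A wrong label for this liver library alone cannot be told, because liver libraries went best with the muscle library of their own mouse in only 3 of 12 mice. A response of this mouse alone stays open too, as untested.

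In other liver libraries, control mouse 801 stood apart with 1.27 FPKM of Cyp4a12a (0 to 0.0285 in the others) and 35.1 of Ndufb3 (67.4 to 72.1), and control mouse 802 with 37.6 of Cyp51 (61.1 to 66.9). Vehicle mouse 814 had 2.27 FPKM of Sult2a2 (0 to 0.110) and 0.164 of Cyp3a41a (0 in the others). Vehicle mouse 770 had 0 FPKM of Cyp3a41b (0.238 to 0.296) and 2.66 of Egln3 (3.50 to 3.64), and vehicle mouse 785 had 1.91 of Tmem88 (1.43 to 1.51). In muscle, control mouse 802 had 4.45 FPKM of Slc2a1 (3.18 to 3.36) and 20053 genes detected (18948 to 19000), control mouse 804 had 5.32 of Gm9531 (3.24 to 3.43) and roxadustat mouse 795 had 6.88 of Myl3 (0.261 to 0.307).

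In WAT, roxadustat mouse 764 stood apart with 49.1 FPKM of Prelp (140 to 202), 4.49 of Egln3 (1.83 to 2.28) and 13.7 of Edem1 (19.4 to 21.3). Roxadustat mouse 767 had 9.95 FPKM of Fos (2.55 to 3.06). Control mouse 779 had 0.0239 FPKM of Vsig8 (0 in the others), control mouse 789 had 1.30 of Ccnb2 (0.440 to 0.475) and control mouse 802 had 6.31 of Edem1 (9.44 to 10.2). Vehicle mouse 814 had 0.963 FPKM of Kif11 (0.257 to 0.437) and vehicle mouse 773 had 4.23 of Sesn2 (10.4 to 16.7).

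The count of genes called for PCOS against control in WAT, 54, was 330 without vehicle mouse 785 and 11 without control mouse 802. A wrong label for the whole of mouse 785 was argued against by its liver and muscle libraries, the lower of which had a position of 1.06. These positions rested on 77 genes in liver and only 7 in muscle. Its WAT library had a position of 0.310 over 330 genes, the lowest of the vehicle libraries. The other vehicle libraries were placed on 14 to 77 genes. The WAT library of mouse 785 also had the fewest genes detected in WAT, 14082, and the fewest genes of 1 to 3 reads, 316. A wrong label or poor quality of this WAT library alone was not tested and stays open. Whether libraries with few genes of 1 to 3 reads are the cause cannot be told, since a term for them lowered the count to 21, where a cause would raise it and no effect would leave it within 1.5 times. An unlike spread of single libraries predicts more calls under sample quality weights, and these gave 940. Such weights let outlying libraries count for less, much as leaving out mouse 785 did, so this rise is no separate evidence. A biological difference between the mice stays open, as untested.

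Epithelial and mesothelial genes were lower in PCOS than in control WAT. A lower share of adipocytes in control samples would raise the markers of all other types there, and the macrophage list argued against that alone, with a median log2 difference of 0.55 in the other direction, although adipocyte markers were higher in PCOS mice in 15 of 18 members, as a lower share in controls predicts (median 0.27, camera adjusted p = 0.0106, or adjusted p = 0.306 with an estimated correlation; 0.0828 without vehicle mouse 785 and 0.0572 without control mouse 802). More mesothelial cells in the control samples is consistent with a second set of mesothelial markers, whose prediction was written before their values were seen. Their median was -0.67, with 7 of 8 lower in PCOS mice and none past the threshold. The fat depot is not named in the labels, and a change of these genes within cells stays open, as untested.

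The PCOS effect differed between tissues, by the test of the difference itself, in 76 genes for liver and muscle, 124 for liver and WAT and 25 for muscle and WAT. With the mouse as a block these were 52, 11 and 0 (627 at an unadjusted p under 0.05 in limma). For liver minus muscle the log2 differences were -7.58 for Cyp2b13, 6.49 for Cyp4a12a and -2.62 for Actr3b (adjusted p = 8.99e-07, 0.000147 and 0.0114 with the block). For liver minus WAT they were -7.61 for Cyp2b13 and 5.03 for Cyp2d9 (0.000313 and 0.00453 with the block). A gene could pass the filter through liver alone, so these differences of Cyp2b13, Cyp4a12a and Cyp2d9 can arise from genes hardly expressed in the other tissue. For muscle minus WAT the log2 differences were 3.06 for Actr3b, 1.99 for Cbr2 and 2.47 for Krt19, and the block ended all 3 calls (adjusted p = 0.423, 0.555 and 0.235). That fit held only mice with both tissues, 12 of 18 libraries. The log2 differences there were 3.54, 2.32 and 2.85, so the effect of the block cannot be told from the loss of mice. Single mice moved these counts by over 1.5 times, to 39 without 785 and 50 without 789 for liver and muscle, and to 389 without 785, 82 without 789 or 814 and 77 without 822 for liver and WAT. For muscle and WAT they gave 54 without 785, 1 without 802, 7 without 773, 11 without 804, 12 without 778 or 822, 13 without 801 or 814, 14 without 779 and 15 without 796.

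Splits of the same libraries were counted for each comparison, the real one included. For PCOS against control in liver, only the real one of 35 splits called at least 115 genes (1 of 35, highest other 1). A chance split is thus unlikely, though 1 of 35 is the smallest share possible. In muscle 2 of 35 called at least 14 (highest other 30), so chance was not excluded. In WAT 2 of 100 called at least 54, so such a count was rare among the splits. The highest other, 725, lay far above the real count, so chance was not firmly excluded. That split put vehicle mice 773 and 785 with the controls, which points to a structure of these samples. For roxadustat against vehicle, where limma called 0 genes (411, 320 and 266 at an unadjusted p under 0.05, and 0 by voom), every split reaches that count (35 of 35, 35 of 35 and 100 of 100, highest other 0, 2 and 3), so the splits decide nothing. Those unadjusted counts lay below the 701, 665 and 766 that chance alone would give. For lists in PCOS against control, 30 of 35 splits called at least 5 in liver (highest other 11), 2 of 35 at least 10 in muscle (11) and 5 of 100 at least 12 in WAT (15), so chance was not excluded. For lists under roxadustat it was not excluded either, with 3 of 35 at least 13 in liver (highest other 14), 32 of 35 at least 4 in muscle (8) and 32 of 100 at least 9 in WAT (13).

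For tissue differences of PCOS, only the real one of 100 regroupings called as many in each pair (1 of 100), with 76 against a highest other of 59, 124 against 6 and 25 against 2. This excluded chance only for the fit without the mouse block, as the regroupings did not keep the libraries of a mouse together, and with the block 52, 11 and 0 genes were called (627 at an unadjusted p under 0.05 in limma). For roxadustat limma called 0 genes (403, 337 and 219 at an unadjusted p under 0.05) in each pair, which all 100 of 100 regroupings reach (highest other 2, 4 and 3), so they decide nothing. For the correlation of PCOS and roxadustat effects 52, 97 and 93 of 100 regroupings were as negative in liver, muscle and WAT as -0.515, -0.151 and -0.0298 (most negative other -0.812, -0.756 and -0.892), so chance was not excluded.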

How the results depend on the processing

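Sample quality weights on log2 FPKM, the term for libraries with few low-count genes, the fits on mice with both tissues only and the contrast of roxadustat with control were chosen only after the results were seen. The edgeR and DESeq2 fits that had been foreseen were not run. Unless a clause says otherwise, the cause of a change was not tested. Of the 16, 7 and 13 named genes called for PCOS in liver, muscle and WAT, 14, 5 and 1 kept their calls whichever mouse was left out. In all alternatives fixed beforehand 3, 3 and 1 kept them, and none changed sign. The calls of named genes were not followed under the alternatives added later. The counts of called genes for PCOS against control in liver stayed between 77 and 166, except 21 with all 3 arms. In muscle the count was 5 with no filter, where more genes are tested, and 6 to 22 leaving out single mice. It was 42 with voom, which also used sample quality weights, and 27 with such weights on log2 FPKM. In WAT it was 10 with no filter, where more genes are tested, 800 with voom, 141 with all 3 arms, 940 with sample quality weights, 21 with the term for few low-count genes, and 11 to 330 leaving out single mice. For roxadustat against vehicle limma called 0 genes in liver and WAT under every alternative run, with 411 and 266 at an unadjusted p under 0.05 in the fits reported and 0 by voom. Chance alone would give about 701 and 766 at that unadjusted p. In muscle it called 2 with no filter and 0 to 1 leaving out single mice.

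Lists called by camera, 5, 10 and 12 for PCOS in liver, muscle and WAT, were 1, 0 and 0 with an estimated correlation and 2, 0 and 3 by fry. For roxadustat 13, 4 and 9 became 0 in each tissue by both (smallest adjusted p = 0.410, 0.894 and 0.690 with an estimated correlation). Leaving out single mice gave 8 to 15 lists for roxadustat in WAT, the highest without roxadustat mouse 764. The male-biased list in liver under roxadustat reversed without roxadustat mouse 808 (adjusted p = 0.333), as that library alone was of the control type, and ranged from 1.84e-06 to 0.333 leaving out single mice. The PCOS difference of liver and WAT was 11 with the mouse block and 24 on the mice with both tissues, which hold fewer mice, and 77 to 389 leaving out single mice. That of muscle and WAT was 0 with the block (627 at an unadjusted p under 0.05 in limma), 1 on the mice with both tissues and 1 to 54 leaving out single mice. That of liver and muscle was 39 to 67 leaving out single mice and 52 with the block. The roxadustat differences of liver with muscle and with WAT were 0 to 1 leaving out single mice. With the PCOS vehicle libraries split, the shared libraries no longer enter. The mean correlation of opposite effects was then -0.141 in liver, 0.251 in muscle and 0.242 in WAT. In WAT single splits ranged from -0.120 to 0.549, so the sign there depended on the split. In muscle the unsplit correlation was -0.354 with no filter. Leaving out single mice gave -0.599 to -0.173 in liver (highest without roxadustat mouse 808), -0.351 to -0.0815 in muscle (lowest without vehicle mouse 770) and -0.190 to 0.141 in WAT (reversed without roxadustat mouse 764).

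For roxadustat against control, limma called 0 genes in liver (1148 at an unadjusted p under 0.05), 1 with no filter and 1 with all 3 arms, and 0 to 157 leaving out single mice. It called 47 in muscle, 16 with no filter and 17 to 33 leaving out single mice. It called 897 in WAT, 197 with no filter, 61 with all 3 arms and 100 to 1771 leaving out single mice. Depth limits genes of few reads, and on simulated data 12% of 2-fold changes were recovered in liver and 16% in WAT for PCOS against control.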

Other observations

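The contrast of roxadustat with control vehicle and its tests were chosen only after the results of the other contrasts were seen, and the tests of its other splits were written before they were run. PCOS mice on roxadustat also differed from controls. In muscle 47 of 13468 genes were called, 38 higher and 9 lower, among them 13 of the 14 genes called for PCOS under vehicle. In WAT 897 of 15499 genes were called, 486 higher and 411 lower, among them 38 of the 54 called under vehicle. The control libraries are shared by both contrasts, so part of this overlap is built in. In 100 simulations with no group difference, which kept the controls shared, limma called at most 0 genes in both, which leaves a difference in 1 contrast alone untested. With the control libraries divided between the contrasts the PCOS and roxadustat contrasts called medians of 3 and 8.5 genes in muscle, with a median of 2 in both, and of 6 and 37 genes in WAT, with a median of 1 in both. In liver limma called 0 of 14152 genes, with 1148 at an unadjusted p under 0.05. No voom fit was run on this contrast.

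Without roxadustat mouse 808, 157 liver genes were called, and 2 without control mouse 802. In muscle single mice gave 26 without control mouse 789, 27 without 802, 17 without 804 and 21 without 801, and 19 without roxadustat mouse 808 and 22 without 782. In WAT they gave 213 without control mouse 778, 312 without 802 and 265 without 779, and 290 without roxadustat mouse 767, 160 without 795, 1771 without 764 and 100 without 809. Of the splits of the same libraries, the real one included, 35 of 35 reach the liver count of 0 by necessity (highest other 65), so they decide nothing there. In muscle only the real one of 35 called as many genes as the real count (real 47, highest other 20), the smallest share possible. A chance split is thus unlikely there. In WAT 2 of 100 did, the real one and 1 other (real 897, highest other 1611). Such a count was rare among the WAT splits, but chance was not firmly excluded. The highest WAT value, above the real count, points to a structure of these samples.

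In the second set of mesothelial markers in WAT, Nkain4 stood at 1.33 ± 0.375 FPKM in PCOS vehicle and 4.23 ± 2.52 in control mice (n = 6 and 4, log2 difference -1.24, limma adjusted p = 0.122). Gpm6a stood at 1.42 ± 1.44 against 3.58 ± 2.23 FPKM and Bnc1 at 0.295 ± 0.283 against 0.961 ± 0.206 FPKM. Cldn15 alone was higher in PCOS mice, at 17.6 ± 2.54 against 15.3 ± 2.70 FPKM.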
